A study of Homo sapiens with 43 samples.

How the data were processed

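Total RNA expression was read on 43 one-colour arrays of human PNT1A cells, with 4 DMSO arrays and 39 arrays of 5 compounds at 2 concentrations. Each array had 62976 spots, of which 58717 were not controls and stood for 42405 probes. Per the file headers, the spot intensity values were extracted from the scanned images with Agilent Feature Extraction 11.5.1.1, and the processed signal used here is the background-corrected intensity on a linear scale. Per the deposited series matrix, the authors also gave log2 values for 29007 probes, scaled between arrays by a method the labels do not state; they are uncentred, with array medians of 7.38 to 7.444. All 43 columns of that matrix matched their own scanner file better than any other array.

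The scanner files were the source of all values in the report. Each processed signal was put on the log2 scale. Spots marked as outliers by the image software were left out, and spots of the same probe were averaged. The 75th percentile of the probe values of the array was then subtracted. A probe was kept when it lay well above background, in the image software's own mark, on at least 3 arrays of at least 1 group, which left 27438 probes. The files carry accessions and no gene names; 26364 probes were matched to a gene symbol through a table of RefSeq genes, and 16041 kept their accession or array name. For each gene the probe of highest mean was used, and 45 genes with a value missing on an array were dropped, leaving 22181 genes, 14815 of them with a symbol. Genome positions are those of build hg19, as in the array files.

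Linear models with 11 group means were fitted to all genes with limma 3.58.1 in R 4.3.3, and moderated with empirical Bayes (32 residual degrees of freedom, prior 2.83, median residual SD 0.248 on the log2 scale). P-values were two-sided and adjusted with the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were each treatment against DMSO, the mean of the 10 treatments against DMSO, any difference among the 11 groups, 1 µM against 10 nM within each compound, and the 5 compounds among each other at each concentration. A gene with no DMSO array, or no treated array, well above background was given as a bound in place of a fitted change. For it, lower signals of that group were raised to the lowest signal marked well above background on the array. Such a bound, written as at least, compares group means and does not allow for the spread between arrays. Unmarked probes can read above this level, as FBXW12 did in DMSO (mean -4.99, 0 of 4 arrays marked). The bounds are therefore not strict lower limits.

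Before the data were examined, 30 gene lists with 442 genes, the groups, the comparisons, most alternatives and the rule for named genes were written down. The lists covered PPAR targets, fatty acid synthesis, cholesterol biosynthesis, aryl hydrocarbon receptor targets, PXR and CAR targets, androgen, estrogen and glucocorticoid response, steroid hormone synthesis, cell cycle, p53 targets, apoptosis, the NRF2, unfolded protein and heat shock responses, metallothioneins, NF-kB and cytokines, interferon response, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, histones, immediate early genes, TGF-beta and matrix, epithelial junctions, and markers of basal, luminal and neuroendocrine epithelium, of leukocytes and endothelium, and of fibroblasts and smooth muscle. Of these genes 390 were tested, and the 27 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over 270 pairs of list and treatment; an estimated correlation was also used. P-values of single genes were in addition adjusted over each list alone.

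By rule, the text names for each treatment the 10 largest rises and 10 largest falls past the threshold with a gene symbol, or, where none passes in a direction, the 3 of smallest p. It names up to 5 each way for the mean of treatments and the dose contrasts (3 where none passes), the 5 of smallest p for tests among groups, the 4 of smallest p of each called list, and a set of genes fixed beforehand; not every gene under the rule is printed. Batches were read from the file headers: 21 arrays on 3 slides in session 1, 15 on 2 slides in session 2 and 7 in session 3.

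Between 60.3% and 70.8% of gene spots lay well above background, and 75th percentile signals ranged from 228 to 468. The steps from gene values to calls were tested on simulated data built on DOM at 1 µM against DMSO. Scaling, filter and probe choice were not part of this test. Over 5 sets with 100 genes changed 2-fold and 100 changed 4-fold, 75.8% and 97% were recovered with 8 to 11 false calls. Sets with no change gave 0 calls, and a list shifted by 0.35 was called in 5 of 5. The simulated noise was independent between arrays and genes, with no slides, sessions or shared cultures. The 0 calls therefore do not give an error rate for these arrays.

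Alternatives were median centring, quantile normalization, normexp correction with quantile normalization, the deposited matrix, other filters and probe summaries, a trended robust fit, blocks for slide and replicate number, fits on the arrays of the compared groups only, and leaving out each array. The files have no mean foreground signal, so normexp, with an offset of 50, used the median foreground and background signals, a departure from the plan. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15; data were read with data.table, version 1.17.8, and statmod 1.5.0 served the random block. Permutation tests drew 1e+05 reassignments for the interferon levels and 10000 for the Mantel test.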

Results

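Gene expression was measured in PNT1A, a line of human prostate epithelial cells immortalised with the SV40 large T antigen and described in the labels as non-cancerous. Cells were exposed for 48 hours to 1 of 5 plasticizer-related compounds or to the vehicle, 0.4% DMSO. The title of the series gives the aim as a screen for green plasticizers. DINCH is diisononyl cyclohexane dicarboxylate, a plasticizer used in place of phthalates, and MEHP is mono(2-ethylhexyl) phthalate, the monoester formed from the phthalate DEHP. DHS, DOM and DOS are not spelled out in the labels and are left as given. The 43 arrays fell into 11 groups: DMSO with 4 arrays, and each compound at 1 µM and at 10 nM with 4 arrays each, except MEHP at 10 nM with 3. The sample labels state these concentrations, while the summary text of the series writes their exponents in another form. Between 60.3% and 70.8% of the gene spots on an array lay well above background, and 0 spots were saturated. Over 63 pairs of arrays from the same group, the log2 difference across genes had an SD of 0.325 to 0.60, and the number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays. Scanning was done in 3 sessions over 8 slides; the 4 DMSO arrays lay in sessions 2 and 3, and 0 of them in session 1.

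The comparison of DOM at 1 µM with DMSO asked which genes differ after exposure to the higher concentration. FAT1, a large atypical cadherin, fell by 0.97 on the log2 scale (SE 0.196, n = 4 and 4, limma adjusted p = 0.0421). CD200, a membrane glycoprotein that restrains myeloid cells, changed by -1.0 (SE 0.175, limma adjusted p = 0.0274). FBN2, the microfibril protein fibrillin-2, changed by -1.0 (SE 0.226), and OLR1, a receptor for oxidised low-density lipoprotein, by -0.92 (SE 0.218). All 4 DOM arrays lay below all 4 DMSO arrays for each of these 4 genes. The Mediator subunit gene MED23 (-0.98, SE 0.217) and the histone demethylase gene KDM6A (-0.87, SE 0.201) also fell. HNMT, which inactivates histamine by methylation, changed by -1.5 (SE 0.354) with 3 of 4 arrays below all DMSO arrays. DPY19L2, a gene needed for sperm head formation, changed by -1.43 (SE 0.299), CCDC117 by -0.93 (SE 0.216) and FAM114A2 by -0.87 (SE 0.206).

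Among 13 tested genes of epithelial junctions, 2 fell in DOM at 1 µM over all genes tested and 4 when adjusted over the list alone. TJP1, a scaffold of tight junctions, changed by -0.50 (SE 0.116, limma adjusted p = 0.0431) and PKP2, a desmosomal plakophilin, by -0.43 (SE 0.105, limma adjusted p = 0.0477), both in 4 of 4 arrays. The E-cadherin gene CDH1 had a log2 value of -0.73 (SE 0.216) and EPCAM, an epithelial adhesion molecule, -0.36 (SE 0.106), each with a limma adjusted p of 0.0682. NRIP1, a coregulator of nuclear receptors from the estrogen response list, changed by -0.57 (SE 0.13, limma adjusted p = 0.043); it was chosen after its values were seen.

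Genes that rose in DOM at 1 µM were more often near background than those that fell. PPP6R1, a regulatory subunit of protein phosphatase 6, rose by 1.07 (SE 0.228, n = 4 and 4, limma adjusted p = 0.0421), and FCRL6, an Fc receptor-like protein of cytotoxic lymphocytes, by 1.75 (SE 0.375). CD3E, a subunit of the T cell receptor complex and a member of the leukocyte list, was at least 2.88-fold higher. It is given as a bound since 0 of the 4 DMSO arrays had signal well above background. Like the other values written as at least, it is not a strict lower limit. For CD3E 2 of 4 DOM arrays exceeded all DMSO arrays, and without DOM replicate 3 it was at least 1.87-fold higher. FAM86JP (1.39, SE 0.315), CD27-AS1 (1.29, SE 0.283), LILRB3 (1.18, SE 0.281), OR6W1P (1.04, SE 0.245), TMEM174 (0.99, SE 0.214), OR1J4 (0.77, SE 0.188) and FCMR (0.70, SE 0.168) also rose. Signal lay well above background on all 43 arrays for 51.2% of the genes that rose and 94.8% of those that fell, against 80.3% of all genes tested.

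In total, limma with Benjamini-Hochberg adjustment called 118 of 22181 genes in DOM at 1 µM, of which 41 rose and 77 fell. With arrays centred on their medians, which put the median of all genes at -0.096, 165 rose and 1174 fell; in the deposited matrix 373 rose and 509 fell. With quantile normalization 1 rose and 9 fell, and with normexp correction as well 3 rose and 30 fell. Without the filter on dim probes, or in a fit of only the arrays compared, 0 genes passed. Replicate number as a block left 2 genes, both falls of the original 118. DOM at 1 µM shared no slide with DMSO arrays. With slide as a block 13 genes passed, 11 rises and 2 falls, with 1 rise and 1 fall of the original 118 among them. Yet the median log2 change of the 77 falls was -0.55 against -0.56 without the block, and that of the 41 rises 0.70 against 1.07. Within scan session 2 the falls had a median of -0.54 and within session 3 of -0.61, from 1 DOM array in each. The falls were picked on these same arrays, so the selection favours such medians and they are no independent support. The count depended on single arrays: it was 48, 1109, 1 and 0 without DMSO replicates 1, 2, 3 and 4, and 0, 0, 1 and 0 without DOM replicates 1, 2, 3 and 4.

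DINCH at 1 µM was compared with DMSO in the same way, and here most of the called genes rose. FCRL6 rose by 2.00 on the log2 scale (SE 0.375, n = 4 and 4, limma adjusted p = 0.0416) in 4 of 4 arrays. PCDH19, a protocadherin, rose by 1.5 (SE 0.342), TRPC2, a pseudogene in humans, by 1.42 (SE 0.267) and XKR9, of the XK family of phospholipid scramblases, by 1.14 (SE 0.255). The growth factor gene FGF4 was at least 2.38-fold higher, LRRC72 at least 2.75-fold and the beta-defensin gene DEFB129 at least 2.40-fold, as 0 of 4 DMSO arrays had signal well above background for any of these 3. CDKN2A-AS1 (1.58, SE 0.352), HCCAT5 (1.22, SE 0.276) and NBPF6 (1.19, SE 0.259) also rose. The 5 falls were DPY19L2 (-1.32, SE 0.299), DOP1B (-0.85, SE 0.193), SLC7A1, a transporter of cationic amino acids (-0.52, SE 0.120), the zinc finger gene ZNF512 (-0.41, SE 0.097) and LYPD6, a modulator of Wnt signalling (-0.40, SE 0.092).

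For DINCH at 1 µM, limma with Benjamini-Hochberg adjustment called 97 genes, of which 92 rose and 5 fell; 23 of the rises carried a gene symbol, and the others were long intergenic RNAs or transcripts known by accession or array name alone. Median centring put the median of all genes at -0.117 and gave 47 rises and 5 falls, and the deposited matrix gave 248 and 55. Quantile normalization gave 0 calls, with or without normexp correction. There were also 0 without the filter on dim probes and 1 in a fit of only the arrays compared. DINCH at 1 µM also shared no slide with DMSO: with slide as a block 0 genes passed, and the median log2 change of the 92 rises went from 1.13 to 0.48 while that of the 5 falls stayed at -0.52. In the only DINCH array of session 2 the median of the rises was 0.56, and in that of session 3 it was 1.54; the falls had -0.15 and -0.78. Without DMSO replicates 2, 3 and 4 the count was 258, 0 and 0, and without DINCH replicates 1, 2, 3 and 4 it was 1476, 0, 229 and 0.

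**Figure D1:**
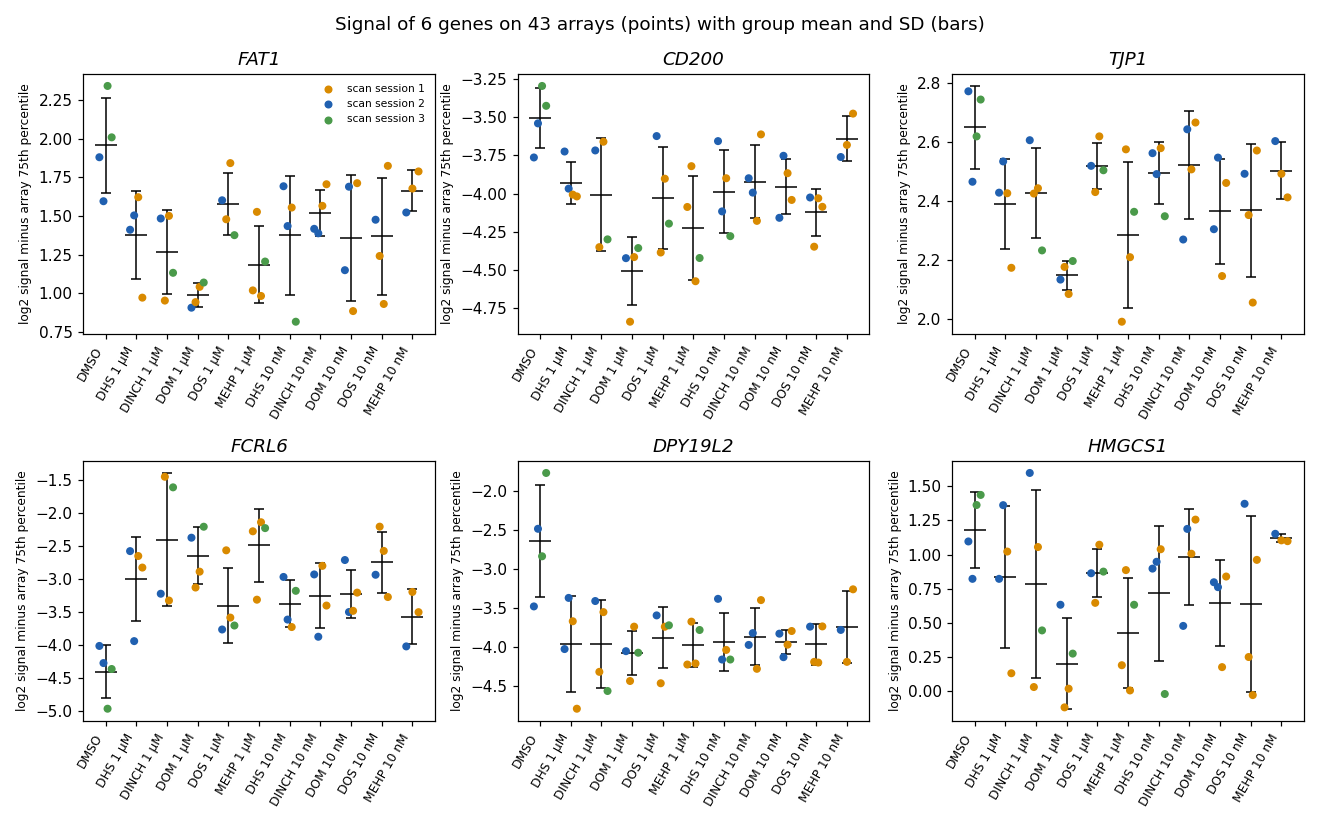
Each panel plots 1 gene (FAT1, CD200, TJP1, FCRL6, DPY19L2 or HMGCS1) as log2 signal minus the 75th percentile of its array (vertical axis) for the 11 groups (horizontal axis); points are arrays coloured by scan session, and bars give the group mean and SD. For FAT1 the 4 DOM 1 µM arrays average 0.99 (SD 0.08) and lie below the 4 DMSO arrays, which average 1.96 (SD 0.31).

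DOM and DINCH at 1 µM called 24 genes in common, 21 that rose and 3 that fell, where independent calls would give 0.170 and 0.0174. The shared falls were DPY19L2, SLC7A1 and LYPD6, and the shared rises with a gene symbol were FCRL6, OR1J4 and OR6W1P. All treatments were compared with the same 4 DMSO arrays, so overlap is expected without any effect. Across the 45 pairs of treatments, fold changes over genes had a mean Pearson r of 0.741 (0.555 to 0.892), against 0.493 in data simulated with no effect; genes are not independent replicates. With the DMSO arrays divided so that the 2 treatments of a pair had different controls, the mean r was 0.265, 0.402 and 0.376 in the 3 possible divisions. The simulation held no slide, session or culture differences, while none of the DMSO arrays lay in session 1. Dividing the controls does not remove such differences. The r values therefore do not show a shared response to the compounds.

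The mean of the 10 treatments was compared with DMSO to find what they had in common. DPY19L2 changed by -1.29 (SE 0.222, limma adjusted p = 0.0109). It lay between -1.43 and -1.22 in the 9 treatments in which it was named, with 32 of 36 arrays below all DMSO arrays. In MEHP at 10 nM, where it was not named, its log2 signal was -3.78, -4.19 and -3.26, against -3.48 to -1.77 in the DMSO arrays. All these values share the same 4 DMSO arrays, so their closeness is not replication. PIGN, an enzyme of GPI anchor synthesis, changed by -1.02 (SE 0.221), HNMT by -1.11 (SE 0.263), the septin gene SEPTIN8 by -0.82 (SE 0.191) and DOP1B by -0.68 (SE 0.143). FCRL6 (1.39, SE 0.278), CDKN2A-AS1 (1.30, SE 0.262) and FCRL1 (1.20, SE 0.288) rose, as did PLPPR5-AS1 and FGF4, for which no size is given because 0 of 4 DMSO arrays had signal well above background.

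For this mean, limma with Benjamini-Hochberg adjustment called 93 genes, 76 that rose and 17 that fell. With slide as a block 9 genes passed, all of them rises, and 0 of the 93 were among them, though all 93 kept their direction. Median centring gave 72 rises and 42 falls, and the deposited matrix 227 and 143. The excess of rises was absent with quantile normalization (1 rise and 1 fall) and with normexp correction as well (0 rises and 4 falls). Signal was well above background on all arrays for 39.5% of the rises and 88.2% of the falls. Without DMSO replicates 1, 2, 3 and 4 the count was 167, 432, 5 and 1. It rose to 222 without DHS 1 µM replicate 2, 148 without DHS 10 nM replicate 4, 361 without DINCH 1 µM replicate 1, 272 without DOS 1 µM replicate 4, 163 without MEHP 1 µM replicate 2 and 199 without MEHP 10 nM replicate 1. It was 61 without DINCH 1 µM replicate 2 or 4, 60 and 61 without DINCH 10 nM replicates 1 and 3, 52 and 59 without DOM 1 µM replicates 1 and 2, and 59 without DOM 10 nM replicate 1. Without DOS 1 µM replicate 2 it was 57, without DOS 10 nM replicates 2 and 3 it was 53 and 58, without MEHP 1 µM replicates 1 and 3 it was 56 and 48, and without MEHP 10 nM replicates 2 and 3 it was 49 and 58. The test of any difference among the 11 groups called 0 genes by limma. It had 1082 at an unadjusted p under 0.05, no more than the 0.05 share of the 22181 genes tested that no difference would give. The 5 genes of smallest p were FCRL6, CD200, FGF4, TRPC2 and SIPA1L3 (limma adjusted p = 0.998).

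At 1 µM, MEHP, DOS and DHS were compared with DMSO to ask the same question of the other compounds. In MEHP at 1 µM the genes nearest the threshold were FCRL6 (1.91, SE 0.375, n = 4 and 4) and the zinc finger gene ZNF10 (-0.50, SE 0.099), both with a limma adjusted p of 0.0626. The death receptor gene FAS had a log2 value of -0.42 (SE 0.099), EID3 -0.54 (SE 0.124), ATRNL1 1.02 (SE 0.216) and DPY19L2 -1.33 (SE 0.299), each with a limma adjusted p of 0.0649. PLPPR5-AS1 was at least 2.33-fold higher, with the same adjusted p from limma. MEHP at 1 µM had 5313 genes at an unadjusted p under 0.05 and 0 past the threshold by limma. Its arrays shared no slide with DMSO arrays. The number past the threshold became 13 without DMSO replicate 1, 369 without DMSO replicate 2 and 1303 without MEHP replicate 2.

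DOS at 1 µM had 1 called gene, a long intergenic noncoding RNA on chromosome 9, forward strand, from 33011575 to 33024766 in build hg19. It rose by 1.09 (SE 0.179, n = 4 and 4, limma adjusted p = 0.0121) in 4 of 4 arrays, and it falls outside the rule for named genes, so it was named after its values were seen. CNMD, which encodes the cartilage protein chondromodulin, was at least 1.92-fold higher with a limma adjusted p of 0.865, TMEM174 had 0.86 (SE 0.214) and the kinase gene NEK3 -0.39 (SE 0.104). ACTL9, well above background on 1 of 4 DOS arrays, was at least 1.92-fold higher and ZNF10 had -0.36 (SE 0.099), both with a limma adjusted p of 0.913. At an unadjusted p under 0.05 there were 963 genes, below the 0.05 share of the 22181 genes tested that no difference would give. The single call was absent, with a count of 0, without DMSO replicate 1, 3 or 4 or without DOS replicate 2 or 4. The count was 2 and 3 without DOS replicates 1 and 3. With quantile normalization it was 0, and in the deposited matrix 12. DHS at 1 µM had 0 called genes by limma and 1719 at an unadjusted p under 0.05; it had 1 call without DMSO replicate 2 and 2 without DHS replicate 2. Its nearest genes were CPA3, a mast cell carboxypeptidase (1.19, SE 0.249, limma adjusted p = 0.177), DPY19L2 (-1.32, SE 0.299) and SPACA3 (0.99, SE 0.245). DEFB129, well above background on 1 of 4 DHS arrays, was at least 2.14-fold higher and CYB5RL at least 2.39-fold lower there, both with a limma adjusted p of 0.308.

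At 10 nM the same 5 compounds were compared with DMSO. DOS gave the values nearest the threshold: STARD9 (0.79, SE 0.170), NBPF6 (1.19, SE 0.259) and CDIN1 (-0.50, SE 0.104), each with a limma adjusted p of 0.122. In DOS at 10 nM CA2, a carbonic anhydrase, had -0.46 (SE 0.110). In DOM at 10 nM PIGN had -1.21 (SE 0.297), the sialidase gene NEU3 1.09 (SE 0.258), NBPF6 1.04 (SE 0.259), and IMMP2L, a mitochondrial peptidase subunit, -0.51 (SE 0.124), while PLPPR5-AS1 was at least 2.17-fold higher. DINCH at 10 nM had FAM111B at 0.51 (SE 0.137), DAPK1, a death-associated kinase, at 0.56 (SE 0.150), CDKN2A-AS1 at 1.33 (SE 0.352), and GNRH1, the gonadotropin-releasing hormone gene, at -0.61 (SE 0.154). ZNF10 was at -0.38 (SE 0.099). DHS at 10 nM had MBTD1 at 0.53 (SE 0.127), RAP1GAP at 1.64 (SE 0.398), IMMP2L at -0.51 (SE 0.124), CA2 at -0.42 (SE 0.110) and PCBP3-AS1 at least 3.11-fold higher (5.34-fold without DHS replicate 2). MEHP at 10 nM, with n = 3, had the neural adhesion gene NCAM2 at 1.78 (SE 0.387), IPMK at 0.51 (SE 0.119), CNTF at 0.93 (SE 0.257), MYO1D at -0.62 (SE 0.140), DOP1B at -0.74 (SE 0.208) and ZNF662 at least 3.09-fold lower. ZNF662 turned to 0.01 with normexp correction and to 0.03 in the deposited matrix.

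None of these passed: limma with Benjamini-Hochberg adjustment called 0 genes in each of the 5 treatments at 10 nM. At an unadjusted p under 0.05 there were 1256 genes for DHS, 1272 for DINCH, 2023 for DOM, 2941 for DOS and 1544 for MEHP. Of these treatments, only DOS shared no slide with DMSO arrays. The median 95% interval of a gene's change, unadjusted for the number of genes, reached 0.352 to either side on the log2 scale, and 0.380 for MEHP at 10 nM. Smaller changes were not resolved for the typical gene, and the adjusted threshold asks for larger ones. In MEHP at 10 nM even NCAM2, at 1.78, had a limma adjusted p of 0.303. The count for DOS became 2 without DMSO replicate 1 and 29 without DMSO replicate 2, and for DINCH 2 and DOM 5 without DMSO replicate 2. It became 1 for DOM without DOM replicate 3, 1 for MEHP without DMSO replicate 1, and 1 for DHS without DMSO replicate 1 or without DHS replicate 1 or 2.

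Genes that mark known targets of plasticizers and of prostate cells were read in every treatment whatever their values. CYP1A1, induced through the aryl hydrocarbon receptor, lay between -0.16 and 0.34 over the 10 treatments. The PPAR targets PDK4 (-0.34 to 0.41), ANGPTL4 (-0.32 to 0.34) and PLIN2 (-0.10 to 0.05), which act in fuel choice, lipoprotein lipase control and lipid droplets, had values on both sides of 0. HMGCS1, an enzyme of the mevalonate pathway, lay between -0.98 and -0.06, lowest in DOM at 1 µM. The keratins had ranges of -0.98 to 0.35 for basal KRT5, -0.52 to -0.12 for luminal KRT8 and -0.10 to 0.07 for KRT18, and the proliferation marker MKI67 of -0.43 to 0.01. None of these genes passed in any of the 10 treatments by limma, and the smallest adjusted p was 0.0693, for HMGCS1 in DOM at 1 µM (-0.98, SE 0.297, 4 of 4 arrays below DMSO). The androgen receptor gene was not among the genes tested.

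Gene lists were tested to ask which pathways moved as groups. Replication-dependent histones, which package newly made DNA, rose as a list in 9 treatments, with medians of 0.31 to 0.46 on the log2 scale (smallest limma camera adjusted p = 5.24e-08; adjusted p = 0.672 at the smallest with an estimated correlation, which was 0.809 between its genes). MEHP at 10 nM had a median of 0.07. Of its 15 genes 0 rose over all genes tested, while 14 rose in DINCH and 6 in DOM at 1 µM when adjusted over the list alone. H4C8 had 0.61 (SE 0.199) and H2AC6 0.51 (SE 0.188) in DINCH at 1 µM, and H2BC4 0.59 (SE 0.203) in DOM at 1 µM. The mean of the list was -1.03 in DMSO replicate 3 against -0.14 to 0.07 in the other DMSO arrays. The median spike-in signal of DMSO replicate 3 was 186.6, the lowest of all arrays, against 345.0 to 388.6 in the other DMSO arrays. Whether the 2 go together was not tested. Without DMSO replicate 3 the medians of the 9 treatments were 0.06 to 0.19, and the list was called higher in 2 treatments and lower in 1. With slide as a block they were 0.14 to 0.33, and it was called higher in 9. In DINCH at 1 µM the list median was -0.14 within session 2 and 1.01 within session 3, with 1 treated array in each.

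The list of epithelial junctions fell in 9 treatments, all but MEHP at 10 nM, with medians reaching -0.36 in DOM at 1 µM and -0.29 in DOM at 10 nM (smallest limma camera adjusted p = 0.00177; adjusted p = 0.672 with an estimated correlation). Over the 10 treatments 2 of its genes fell over all genes tested, both in DOM at 1 µM, against 7 falls adjusted over the list alone. CDH1 had -0.51 (SE 0.216) in DOM at 10 nM, TJP1 -0.37 (SE 0.116) in MEHP at 1 µM, the desmoplakin gene DSP -0.40 (SE 0.196) in DINCH at 1 µM and the claudin gene CLDN1 -0.63 (SE 0.331) in DHS at 10 nM. The list was called in 7 treatments without DMSO replicate 3 and in 4 with slide as a block, while the medians of the 9 treatments, -0.36 to -0.13, were -0.29 to -0.13 and -0.41 to -0.12. The histone and junction lists kept their direction in these calls under median centring, quantile normalization, normexp correction and in the deposited matrix. So did every other called list except ribosomal proteins. Each scaling uses the same DMSO arrays.

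Targets of p53, the DNA damage regulator, fell as a list in 8 treatments, with medians reaching -0.22 in MEHP at 1 µM (smallest limma camera adjusted p = 0.00134; adjusted p = 0.672 with an estimated correlation). Of 19 genes 0 fell over all genes tested, against 9 falls over all treatments adjusted over the list alone: FAS is 1 example, TP53INP1 had -1.09 (SE 0.305) in DOM at 1 µM and SESN1, which restrains growth signalling, -0.66 (SE 0.238) in MEHP at 1 µM. The SV40 large T antigen of this line binds p53. The unfolded protein response list fell in 7 treatments (smallest limma camera adjusted p = 0.00169; adjusted p = 0.672 with an estimated correlation), with a median of -0.18 in MEHP and -0.14 in DOM at 1 µM. Of its 19 genes 0 fell over all genes tested and there were 9 falls adjusted over the list alone; the transcription factor gene XBP1 had -0.31 (SE 0.088) and the chaperone gene DNAJB9 -0.35 (SE 0.116) in MEHP at 1 µM, and the disulfide isomerase gene PDIA4 -0.81 (SE 0.256) in DOM at 1 µM. The p53 list was called in 0 treatments with slide as a block, where its medians went from between -0.22 and -0.10 to between -0.16 and 0.03, the last in DINCH at 1 µM. The unfolded protein list was called in 1, with medians of -0.18 to -0.08 before and -0.15 to -0.04 after. Without DMSO replicate 3 the p53 list was called in 2, with medians of -0.22 to -0.06, and without DMSO replicate 4 in 5, and the unfolded protein list in 3 without DMSO replicate 1 and 2 without DMSO replicate 4.

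The cell cycle list fell in 4 treatments (smallest limma camera adjusted p = 0.0223; adjusted p = 0.672 with an estimated correlation) and in 0 with slide as a block. Of its 25 genes 0 fell over all genes tested and 3 when adjusted over the list alone, in DOM at 1 µM, where the topoisomerase gene TOP2A had -0.83 (SE 0.274), the ribonucleotide reductase gene RRM2 -0.90 (SE 0.300) and the helicase subunit gene MCM6 -0.36 (SE 0.119). Hypoxia and glycolysis genes fell as a list in DOM, DOS and MEHP at 10 nM (smallest limma camera adjusted p = 0.0167; adjusted p = 0.672 with an estimated correlation), and in all 10 treatments with slide as a block; of 17 genes 0 fell over all genes tested. Adjusted over the list alone 1 fell, in DOM at 1 µM, where the list was not called without the block (limma camera adjusted p = 0.288; 0.768 with an estimated correlation). Without DMSO replicate 1 the hypoxia list was called in 0 treatments, without DMSO replicate 2 in 1 and without DMSO replicate 3 in 7, and the cell cycle list was called in 1 without DMSO replicate 1 and in 2 without DMSO replicate 3. KDM3A, a hypoxia-induced demethylase, had -0.35 (SE 0.146) in DOM at 10 nM.

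Cholesterol biosynthesis genes fell as a list in DOM at 1 µM alone among the treatments, with a median of -0.17 (limma camera adjusted p = 0.0283; adjusted p = 0.672 with an estimated correlation); the difference between treatments was not tested. Of 24 genes 0 fell over all genes tested and 4 when adjusted over the list alone, with HMGCS1 at -0.98, MSMO1 at -0.89 (SE 0.302) and STARD4 at -0.43 (SE 0.147). This call ended with slide as a block, where 3 treatments were called higher. It was also absent without DMSO replicate 2 or 4. The NRF2 oxidative stress list fell in DINCH at 1 µM (median -0.17, limma camera adjusted p = 0.0308; adjusted p = 0.672 with an estimated correlation), where of 16 genes 0 fell by either adjustment. There ME1 had -0.42 (SE 0.232) and NQO1 -0.40 (SE 0.248). NF-kB and inflammatory cytokine genes rose as a list in DINCH at 10 nM (median 0.16, limma camera adjusted p = 0.0283; adjusted p = 0.672 with an estimated correlation), where of 14 genes 0 rose by either adjustment. There the chemokine genes CXCL1 and CXCL8 had 0.58 (SE 0.230) and 0.54 (SE 0.224). Both calls ended with slide as a block and without DMSO replicate 3. The block turned the NRF2 direction in DINCH at 1 µM to higher (limma camera adjusted p = 0.762), and NRF2 genes were called higher in MEHP at 10 nM. The NRF2 call also ended without DMSO replicate 2, and the NF-kB call also without DMSO replicate 1. The NRF2 list was called lower in 3 treatments without DMSO replicate 1 and in 4 without DMSO replicate 4.

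Ribosomal protein genes rose as a list in DINCH and DOS at 1 µM and DHS at 10 nM (smallest limma camera adjusted p = 0.00427; adjusted p = 0.713 with an estimated correlation), but the median turned below 0 in all 3 with normexp correction, in 2 in the deposited matrix and in 1 with quantile normalization. Of 24 genes 0 rose by either adjustment; RPS20 had 0.28 (SE 0.089) and RPL19 0.21 (SE 0.095) in DINCH at 1 µM, and the list was called in 0 treatments without DMSO replicate 3 and in 5 without DMSO replicate 1. In all, camera called 46 of 270 pairs of list and treatment, 0 of them with an estimated correlation, where 13 had an unadjusted p under 0.05. Of the 46, 19 remained with slide as a block and 39 with session as a block. Median, mean and test had the same sign in each of the 46.

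The other 17 lists had no camera call. Steroid-related lists had medians of -0.07 to 0.08 for androgen response (14 genes, smallest limma camera adjusted p = 0.699), -0.26 to 0.03 for estrogen response (12 genes, 0.0957), -0.13 to -0.02 for glucocorticoid response (10 genes, 0.153) and -0.06 to 0.08 for steroid hormone synthesis (8 genes, 0.382). Lipid and xenobiotic lists had medians of -0.05 to 0.14 for PPAR targets (18 genes, smallest limma camera adjusted p = 0.325), -0.12 to 0.00 for fatty acid synthesis (13 genes, 0.0703) and -0.12 to 0.10 for aryl hydrocarbon receptor targets (7 genes, 0.272). Stress and death lists had medians of -0.19 to 0.02 for apoptosis (18 genes, smallest limma camera adjusted p = 0.0658), -0.06 to 0.00 for heat shock (11 genes, 0.275), -0.01 to 0.30 for metallothioneins (10 genes, 0.0908) and -0.15 to -0.02 for immediate early genes (13 genes, 0.0657). Interferon response genes had -0.12 to 0.31 (21 genes, smallest limma camera adjusted p = 0.10), oxidative phosphorylation -0.03 to 0.08 (19 genes, 0.145) and TGF-beta and matrix genes -0.22 to 0.00 (15 genes, 0.108). With slide as a block calls were gained, of which 0 passed with an estimated correlation as well: PPAR targets higher in DOM and DOS at 1 µM (smallest limma camera adjusted p = 0.0147), interferon genes higher in 2 treatments (0.00112), aryl hydrocarbon receptor targets higher in MEHP at 10 nM (0.0495) and oxidative phosphorylation higher in 7 (0.00566). Immediate early genes were called lower in MEHP at 1 µM (0.00976) and TGF-beta and matrix genes in DOM at 1 µM (0.0391). Without DMSO replicate 1 fatty acid synthesis was called lower in 6 treatments, interferon genes in 4 and immediate early genes in 1. Interferon genes were called higher in 1 treatment without DMSO replicate 3 or 4, and without DMSO replicate 3 TGF-beta and matrix genes were lower in 1.

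Cell type markers had medians of -0.16 to 0.03 for basal epithelium (8 genes, smallest limma camera adjusted p = 0.133), -0.14 to 0.04 for luminal epithelium (5 genes, 0.153) and 0.05 to 0.23 for leukocyte and endothelial markers (6 genes, 0.256). Over all genes tested, the estrogen list had 1 fall, NRIP1, the leukocyte list 1 rise, CD3E, and the other 15 uncalled lists 0 genes. Adjusted over the list alone and summed over treatments, there were 4 falls in the estrogen list, 4 rises in the leukocyte list, 4 rises in metallothioneins, 3 falls in fatty acid synthesis, 3 rises and 1 fall in androgen response, 2 rises in steroid synthesis, 2 falls in luminal markers, 1 rise in PPAR targets, and 1 rise and 2 falls in TGF-beta and matrix genes. PXR and CAR targets, with 3 genes tested, and neuroendocrine and fibroblast markers, with 4 each, were too few for the test.

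**Figure D2:**
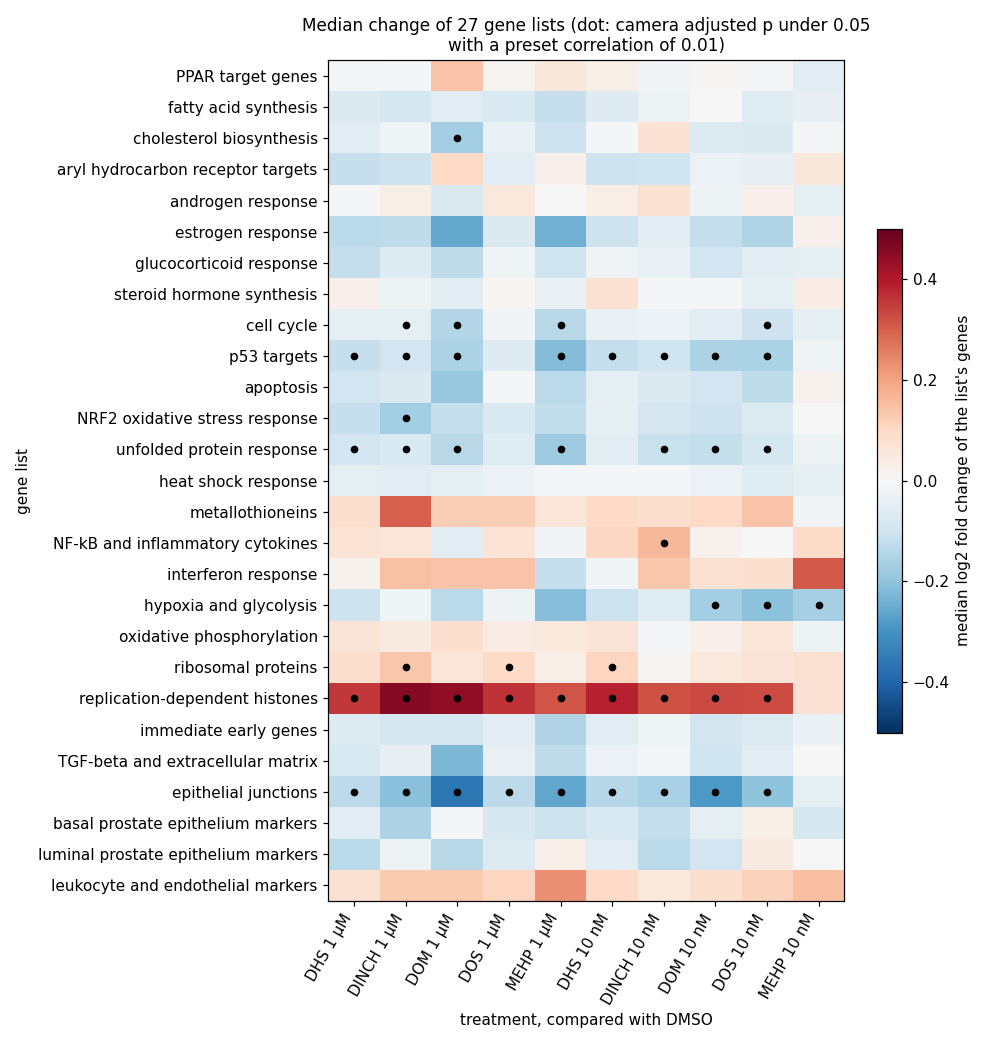
The colour gives the median log2 fold change against DMSO of the genes of 27 lists (vertical axis) in 10 treatments (horizontal axis); dots mark camera adjusted p-values under 0.05 with a preset correlation of 0.01, none of which passed with an estimated correlation. Histone genes have medians of 0.31 to 0.46 in the 9 treatments with a dot, and junction genes reach -0.36; the ribosomal medians turn below 0 with normexp correction.

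The 2 concentrations of each compound were compared directly to ask whether the response depended on dose. For DOM, PPP6R1 had a log2 difference of 0.87 (SE 0.228) between 1 µM and 10 nM, the endothelial adhesion gene ESAM 0.98 (SE 0.288), and LGR4, a receptor for R-spondins, -0.54 (SE 0.159), each with a limma adjusted p of 0.995. For DINCH, the heat shock gene HSPA6 had 0.81 (SE 0.195), HCCAT5 1.07 (SE 0.276), TRPC2 0.98 (SE 0.267) and CLSPN, a checkpoint mediator, -0.57 (SE 0.183). For MEHP, MADCAM1, a mucosal addressin, had 1.58 (SE 0.354), MIR600HG 1.44 (SE 0.343) and RNLS -0.95 (SE 0.276), each with a limma adjusted p of 0.652. For DHS, RPL3L had 0.61 (SE 0.166) and RAP1GAP -1.47 (SE 0.398), and for DOS, IPPK had 1.1 (SE 0.276) and ABHD1 -1.15 (SE 0.312). In each of these 5 contrasts limma with Benjamini-Hochberg adjustment called 0 genes. At an unadjusted p under 0.05 there were 355 for DHS, 518 for DINCH, 367 for DOM, 391 for DOS and 1559 for MEHP. All but MEHP lie below the 0.05 share of the 22181 genes tested that no difference would give. The DHS contrast had 1 call without DHS 10 nM replicate 1 or without DHS 10 nM replicate 4. The calls made at 1 µM and missed at 10 nM were therefore not shown to differ between concentrations.

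The 5 compounds were compared with each other at matched concentration and time. At 1 µM the genes of smallest p were PRDM6, DZANK1, IPPK, ZNF547 and OR10C1, and at 10 nM CCDC40, HAS1, a hyaluronan synthase, FAM81A, ZNF780B and WFIKKN1, each with a limma adjusted p of 1. The test among the 5 compounds called 0 genes by limma at 1 µM and 0 at 10 nM, the latter becoming 1 without DHS 10 nM replicate 1. At an unadjusted p under 0.05 it had 492 genes at 1 µM and 324 at 10 nM. Both are below the 0.05 share of the 22181 genes tested that no difference would give. Each of the 20 contrasts between 2 compounds also had 0 genes by limma. At an unadjusted p under 0.05 they had 186 to 1758 genes at 1 µM, on both sides of that share. At 10 nM they had 209 to 651, all below it. The smallest limma adjusted p-values were 0.395 and 0.128. The median 95% interval of such a difference reached 0.352 to either side, or 0.380 with MEHP at 10 nM, and missing the threshold does not show that the compounds act alike.

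**Figure D3:**
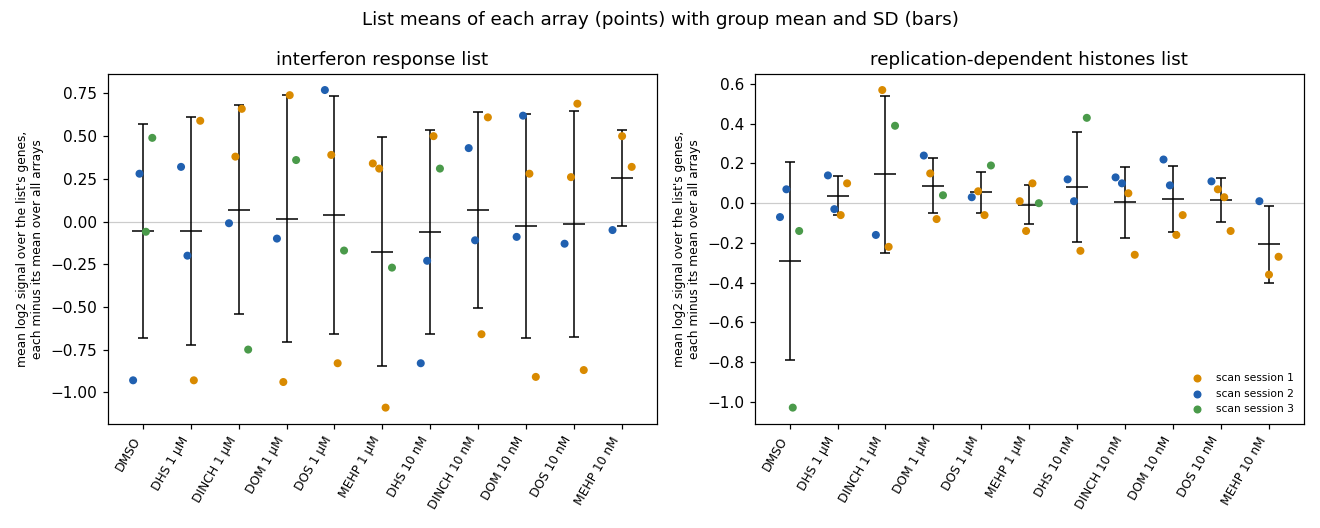
Mean log2 signal over the genes of the interferon list (left) and the histone list (right), each gene minus its mean over all arrays (vertical axis), for the 11 groups (horizontal axis); points are arrays coloured by scan session, and bars give the group mean and SD. In the 10 groups of 4 arrays the interferon means fall at similar levels. The lowest array lies between -1.09 and -0.66 and the highest between 0.34 and 0.77. The histone mean is lowest in 1 DMSO array, replicate 3. With that array included, the histone medians are above 0 in all 10 treatments under each scaling. With it left out, the median in MEHP at 10 nM is -0.16.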

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

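The tests of slide, of the 4 matching interferon levels, of session and replicate number, and of the histone list were chosen after the result was seen; those of DMSO replicate 3 on the called genes, of similarity outside the interferon list and of other splits of the arrays were chosen before. Within groups of 4 arrays, 13 of 172 sets of values had 1 array far from the other 3, where chance alone gives about 1 in 20. For genes, in log2 signal relative to the array's 75th percentile, CD3E read -2.18 in DOM 1 µM replicate 3 against -4.84 to -4.40 in the others, and PPP6R1 read 0.01 in the same array against -1.14 to -0.99. CD200 read -4.84 in DOM 1 µM replicate 2 (others -4.42 to -4.36), DEFB129 -4.89 in DINCH 1 µM replicate 4 (-4.65 to -4.63), FGF4 -7.02 in DMSO replicate 4 (-6.19 to -6.09) and KDM6A -0.50 in DMSO replicate 2 (0.00 to 0.04). For list means, the cell cycle list read -0.17 in MEHP 1 µM replicate 1 and 0.12 in DINCH 10 nM replicate 2 (both others -0.03 to -0.01). Ribosomal proteins read -0.14 in DOM 10 nM replicate 3 (0.03 to 0.05), and p53 targets -0.10 in DOS 10 nM replicate 4 (-0.04 to -0.03). The median spike-in signal was 501.1 in DHS 1 µM replicate 4 (298.8 to 312.3) and 451.1 in DOS 10 nM replicate 4 (318.9 to 336.9), and 69.3% of spots lay well above background in DINCH 10 nM replicate 4 (64.52 to 65.1). No explanation was tested for these single arrays.

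The first pattern is the set of genes called in DINCH and DOM at 1 µM, neither of which shared a slide with DMSO. MEHP at 1 µM and DOS at 10 nM shared none either. At an unadjusted p under 0.05, DOM, MEHP and DINCH at 1 µM had 5788, 5313 and 3854 genes, and DOS at 10 nM had 2941. Every other treatment shared a slide with DMSO and had at most 2023. These counts therefore go with slide as well as with compound. With slide as a block, the median ratio of the new to the original log2 change was 0.45 for the 92 rises of DINCH. Differences between slides may therefore carry much of them. The ratio was 0.93 for the 5 falls of DINCH and 0.92 for the 77 falls of DOM, which argues against slide as their main cause. For the 41 rises of DOM it was 0.66 and does not decide. With no shared slide, the block compares these treatments with DMSO only through other treatments, so slide was not excluded. The ratios without DMSO replicate 3 were 0.90 and 1.01 for DINCH rises and falls and 0.91 and 0.94 for DOM rises and falls. A gene moved by that array alone would also have a wide residual spread and would seldom be called. The ratios of called genes could therefore hardly come out low, and they do not decide on that array. With it left out, 0 genes were called for DINCH and 1 for DOM. An effect of the compounds stays open for the falls and the DOM rises. It is also not excluded for the DINCH rises, whose median was 0.48 with the block. Still, only 1 rise and 1 fall of the 118 DOM genes, and 0 of the 97 DINCH genes, passed with the block.

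Histone genes were higher in treated arrays in 9 treatments. Without DMSO replicate 3 the list was called higher in 2 and its medians had a median ratio of 0.28 to the original ones, so that array may carry much of the pattern. With slide as a block it was called in 9 with a median ratio of 0.62, which does not decide on differences between slides. Replicate 3 is the only array of its slide and has no weight in that fit, so the calls there argue against replicate 3 as the whole cause. They do not exclude it, since none passed with an estimated correlation, and whether the compounds raise histone transcripts stays open.

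The interferon list spread widely within groups, with an estimated correlation between its genes of 0.889. Sorted within each of the 10 groups of 4 arrays, its means averaged -0.87, -0.14, 0.33 and 0.60 and matched across groups with SDs of 0.12, 0.08, 0.06 and 0.13, against 0.37 under reassignment (permutation p = 1e-05, the smallest these permutations can give), so each group may hold arrays from the same 4 culture lots. Arrays close in the list were also alike in 17796 genes outside it (Mantel r = -0.387 over 840 pairs between distance and similarity, permutation p = 1e-04, the smallest possible). Slide (permutation p = 0.947), session (permutation p = 0.984) and replicate number (permutation p = 0.895) took no larger share of the spread than permuted labels. The labels name no lots, so this stays a hypothesis, and no biological explanation was tested. The comparisons with DMSO did not model such lots. With the interferon list mean as a covariate, chosen after the result was seen, DOM at 1 µM had 348 genes, DINCH at 1 µM 151 and the mean of treatments 201.

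Other splits of the same arrays were fitted in the same way. For DOM at 1 µM, 1 of 35 splits, the real one, gave as many genes as the real 118 (highest other 2). For the mean of treatments 1 of 100 gave as many as 93 (highest other 20). In both the real split gave the most genes, which is the smallest share such splits can give. DOM at 1 µM was also 1 of 10 treatments split in this way, so chance was not excluded. These splits ignore slide and any shared culture lots. With slide as a block DOM at 1 µM had 13 genes, with 1 rise and 1 fall of the 118 among them. The mean had 9, with 0 of the 93 among them. For DINCH at 1 µM, 2 of 35 splits gave as many as 97 (highest other 475), and for DOS at 1 µM 6 of 35 as many as 1 (highest other 83); chance cannot be excluded. The larger split for DINCH exchanged DINCH replicate 1 with DMSO replicate 2, both of session 2, that for DOS exchanged DOS replicate 4 with DMSO replicate 2, and counts several times the real one point to a structure of the samples other than treatment. The DINCH count was 0 with slide as a block and 64 with session as a block. For a real count of 0, all 35 of 35 splits are as large by necessity: the highest other was 8 for DHS, 1 for MEHP at 1 µM, and 26, 1, 2, 0 and 10 for DHS, DINCH, DOM, DOS and MEHP at 10 nM. The 26 came from exchanging DHS 10 nM replicate 4 with DMSO replicate 2. The dose contrasts, also with 0 genes and 35 of 35, had highest others of 0, 0, 0, 1 and 1 for DHS, DINCH, DOM, DOS and MEHP. Among the 11 groups 100 of 100 splits were as large as 0 (highest other 2712, whose cause was not tested), and among the 5 compounds 100 of 100 (5 at 1 µM, 1 at 10 nM). For the gene lists 17 of 50 regroupings of the arrays gave as many pairs as 46 (highest other 70), so chance cannot be excluded for the number of list calls.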

How the results depend on the processing

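The tests with session as a block, within single sessions, with slide as a random block, with the interferon list as a covariate, with shuffled replicate numbers, and with slide and an estimated correlation together were chosen after the result was seen. Values are genes past the threshold, against 97 for DINCH 1 µM, 118 for DOM 1 µM, 1 for DOS 1 µM, 93 for the mean of treatments, 0 for the other treatments, and 46 list calls. Under alternatives other than leaving out arrays, 221 such results stayed within 1.5 times and 80 moved. Those that stayed include counts of 0 that remained 0, and most comparisons had 0 in the main fit. The cause of the moves was not tested. Median centring gave DINCH 1 µM 52 and DOM 1 µM 1339. Quantile normalization gave DHS 1 µM 1, DINCH 1 µM 0, DOM 1 µM 10, DOS 1 µM 0, the mean 2 and 29 list calls. Normexp with quantile normalization gave DINCH 1 µM 0, DOM 1 µM 33, DOS 1 µM 0 and the mean 4. ZNF662 in MEHP 10 nM then turned to 0.01. The deposited matrix gave DHS 1 µM 6, DINCH 1 µM 303, DOM 1 µM 882, DOS 1 µM 12, MEHP 1 µM 187, DHS 10 nM 12, DINCH 10 nM 2, DOM 10 nM 9, DOS 10 nM 15 and the mean 370. There ZNF662 in MEHP 10 nM turned to 0.03. Without the filter on dim probes DINCH 1 µM had 0, DOM 1 µM 0, DOS 1 µM 2 and the mean 19; with signal well above background on all arrays DINCH 1 µM had 59 and the mean 19. A mean over probes gave DOM 1 µM 78, and PFKFB3 in DOS 10 nM turned to 0.12 and RPL22 in DOS 1 µM to -0.02. A trended robust fit gave DOS 1 µM 2 and the mean 61. Fitting only the arrays compared gave DINCH 1 µM 1, DOM 1 µM 0, DOS 1 µM 0, DOS 10 nM 1 and MEHP 1 µM 22. At an unadjusted p under 0.05 and 1.5-fold, counts were 805 for DHS 1 µM, 1716 for DINCH 1 µM, 1912 for DOM 1 µM, 420 for DOS 1 µM, 2049 for MEHP 1 µM, 485 for DHS 10 nM, 520 for DINCH 10 nM, 748 for DOM 10 nM, 1180 for DOS 10 nM, 760 for MEHP 10 nM and 926 for the mean. With slide as a fixed block they were DHS 1 µM 2, DINCH 1 µM 0, DOM 1 µM 13, DOS 1 µM 3, DHS 10 nM 7, DINCH 10 nM 3, DOM 10 nM 4, MEHP 10 nM 2 and the mean 9. PLIN2 in DOM 10 nM turned to 0.08 and SLC7A11 in DINCH 1 µM to 0.09. Slide as a random block gave DINCH 1 µM 0, DOM 1 µM 10 and the mean 4. Session as a fixed block gave DHS 1 µM 1, DINCH 1 µM 64, DOS 1 µM 5, MEHP 1 µM 2, DHS 10 nM 4, DINCH 10 nM 1, DOM 10 nM 3, DOS 10 nM 1 and the mean 36. PLIN2 in DOM 10 nM turned to 0.01. Within session 2 DINCH 1 µM had 0, DOM 1 µM 1 and DOS 1 µM 11, and within session 3 all 3 had 0, each with 1 treated array of DINCH and of DOM assumed to vary like the other groups. The interferon list as a covariate gave DINCH 1 µM 151, DOM 1 µM 348 and the mean 201. With an estimated correlation 0 list calls passed, and 0 with slide as a block as well. Replicate number as a replicate block gave DOM 1 µM 2, but the numbers were not taken to pair the arrays, since 13 of 39 same-number pairs with DMSO correlated over 0.1. These pairs read 0.123, 0.069, 0.152 and 0.311 for DOM 1 µM and 0.028, 0.287, 0.252 and 0.182 for DINCH 1 µM. Pairs of the other treatments lay on both sides of 0 and reached down to -0.274. A pairing in DOM and DINCH at 1 µM was therefore not excluded. Deviations from the group means correlated at 0.042 on average for the same number against -0.014 for other numbers (permutation p = 0.00981). Of 43 arrays 19 were closest to their own number, against 10.8 with numbers shuffled within groups (permutation p = 0.0266) and 21.6 shuffled within groups and scan sessions (permutation p = 0.849), so scan session could account for the likeness. Shuffling within sessions can exchange only arrays of a group that share a session, so it is a weak test. Leaving out each array gave ranges of 0 to 2 for DHS 1 µM, 0 to 1476 for DINCH 1 µM, 0 to 1109 for DOM 1 µM, 0 to 3 for DOS 1 µM, and 0 to 1303 for MEHP 1 µM. At the lower concentration they were 0 to 1 for DHS 10 nM, 0 to 2 for DINCH 10 nM, 0 to 5 for DOM 10 nM, 0 to 29 for DOS 10 nM, 0 to 1 for MEHP 10 nM, and 1 to 432 for the mean. They were 31 to 51 for list calls (leaving out DMSO arrays only), 0 to 1 for the DHS dose contrast and for compounds at 10 nM, and 0 to 0 for the other dose contrasts, the 11 groups and compounds at 1 µM. BAX in DINCH 10 nM turned to 0.06 without DINCH 10 nM replicate 1 and was -0.42 without DINCH 10 nM replicate 2. Of single named genes under the other alternatives, 3935 values kept direction and side of the threshold, 340 became weaker, 40 stronger and 7 reversed. Signal over background also limits the rises: 39.5% of those of the mean of treatments lay well above background on all arrays.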
